A study of Mus musculus with 19 samples.

How the data were processed

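The series compares dorsal root ganglion neurons sorted from genetically labelled mice, MrgprA3+ by green fluorescence and MrgprA3- by a gate matched to the shape of the labelled cells. Per the labels, ACD was produced in male C57BL/6 mice of 2 months with squaric acid dibutylester on the abdomen and then on the lower back, controls received acetone, 5 mice were used per treatment, and both populations were sorted from the ganglia T11 to L6 of every mouse on day 13. RNA was isolated with RNeasy Micro kits and polyadenylated libraries were sequenced, per the labels. According to the submitters' processing notes reads were aligned with Bowtie2 to mm9; the version of Bowtie2, the gene annotation, the quantification program and the read length are not given in the sources used here.

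The values analysed were FPKM computed by the authors and deposited as 1 table of 18666 genes with 2 decimals, and no further scaling between libraries is stated in the sources used here. Raw reads were not used here. Each library was matched to its label by its column header, which gave 5 libraries in each of 3 groups and 4 in MrgprA3+ neurons of ACD mice, where replicate 3 was not analysed here. In the symbol column 25 entries had been turned into dates and 8 were a dash; 25 of these damaged entries were given back a symbol through their gene identifier, and the rest were named by the identifier. No symbol occurred more than once and 20 genes were 0 in all libraries. Gene positions were not used, because the files refer to mm9 and the reference at hand to GRCm38.

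Sequencing depth, estimated from the spacing of low FPKM values of 1080 single-transcript genes of 300 to 900 bp, lay between 10.3 and 21.2 M fragments (M, 1e+06) (group means 13.1 in MrgprA3+ control, 15.1 in MrgprA3- control, 15.0 in MrgprA3+ ACD and 16.3 in MrgprA3- ACD libraries). Between 73.6% and 83.7% of the low values lay within 0.2 of a whole step, against 40% by chance for a step fixed in advance. The step was chosen to fit these same values, which raises the share reached by chance, and that share was not computed. The transcript lengths came from GRCm38, so the depths are approximate.

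The groups, comparisons, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Genes with at least 1 FPKM in at least 4 of the 19 libraries were kept (11996 genes). Group means of log2(FPKM + 1) over all 19 libraries were fitted with limma 3.58.1 (lmFit, contrasts.fit, eBayes with trend and robust options; statmod 1.5.0) in R 4.3.3, and p-values were two-sided and adjusted by Benjamini and Hochberg over the genes kept, with a threshold of 0.05. Fold changes are differences of mean log2(FPKM + 1), which understate the change of genes at low FPKM; errors are standard errors of the model (SE), and errors of mean FPKM are standard deviations. A gene is said to rise or fall where it passed that threshold.

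Of 36 gene lists 31 had at least 5 members kept and were tested by camera (limma) with a preset correlation between genes of 0.01, adjusted over the lists of each comparison; camera with the correlation estimated from the data and fry were run as alternatives, and the adjusted p from the estimated correlation is given as p with estimated correlation where the preset value passed. The lists of cold sensors, endothelium, fibroblasts and mural cells, red blood cells and sex-linked genes had fewer members kept and were not tested. The correlation between genes of a list was estimated at up to 0.612 (ribosomal proteins), and only 11 of the 44 list results past the threshold kept it with the estimated correlation. Besides the lists, the 10 largest rises and falls per comparison among genes with at least 5 FPKM in the higher group, the genes with the smallest p where few passed, and a fixed set (Mrgpra3, Hrh1, Trpa1, Trpv1, Nppb, Sst, Mrgprd, Calca, Tac1, Th, Nefh, Ccl2 and Cxcl10) could be named; Cxcl10 did not pass the expression filter. Per-library values were compared by exact permutation of the group labels, with a smallest possible two-sided p of 0.00794.

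Simulated data, 1 set per comparison, had each population's own spread, 200 genes changed and each gene drawn independently. The shared fit then gave 8.21% false results for the population difference in control mice and 12.2% in ACD mice. Fits to the libraries of the compared groups alone gave 12.4% and 19.3%. Those shares need not hold for another number of changed genes. For dermatitis the shared fit gave 51.4% false results in MrgprA3+ neurons and 1.67% in MrgprA3- neurons. Fits to the libraries of the compared groups alone gave 4.11% and 4.27% for dermatitis. The shared fit is thus too permissive for dermatitis in the MrgprA3+ and too strict in the MrgprA3- neurons, and under dermatitis the gene counts and the lists past the threshold are given from both fits.

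Alternatives were a pseudocount of 0.1, no filter or a stricter filter (at least 5 FPKM), median-ratio and quantile rescaling, limma library weights, only the libraries compared, each library left out in turn, a threshold of 1 on the absolute log2 change, glial list means as covariates, and the mouse as a replicate block or random effect. Added after results were seen were a fit without the MrgprA3+ library of largest spread in each treatment, the list tests after rescaling and the list tests with each library left out in turn. The labels state that both populations came from every animal and do not state that the replicate number is the animal, which is assumed for the block; after removal of group means, libraries with the same number correlated by 0.0746 on average over 9 pairs (-0.0563 to 0.193), and 5 of 9 matched their own partner best. That is weak evidence for the pairing, and the tests therefore treat libraries as independent; with the mouse as replicate block 3123 genes passed in control and 2399 in ACD mice. Under dermatitis the block was the replicate number alone, since the mice differ between treatments. Behaviour and histology were not analysed here. Results for some single genes are not reported here.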

Results

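Sensory neurons carrying the MrgprA3 label were compared with unlabelled neurons of the same dorsal root ganglia, in control mice and in mice with allergic contact dermatitis (ACD). The 19 libraries were 5 MrgprA3+ and 5 MrgprA3- libraries of control mice and 4 MrgprA3+ and 5 MrgprA3- libraries of ACD mice, and per the labels both populations were collected from every one of 5 mice per treatment. Estimated depth lay between 10.3 and 21.2 M fragments per library. Mrgpra3 itself averaged 1131 FPKM (SD 197, n = 5) in the MrgprA3+ and 20.2 FPKM (SD 4.12, n = 5) in the MrgprA3- libraries of control mice, and 940 (SD 101, n = 4) against 19.96 FPKM (SD 3.97, n = 5) in ACD mice. The differences of 5.74 and 5.50 in log2(FPKM + 1) each had an exact two-sided permutation p of 0.00794, the smallest that either design allows. Unless another fit is named, the gene p-values below rest on a spread between libraries pooled over all 4 groups, with no term for the mouse.

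In control mice, receptors of the Mas-related family, several of which bind pruritogens, were higher in MrgprA3+ than in MrgprA3- neurons. Mrgprb4 rose 5.22 in log2 (SE 0.33; 61.5 against 0.518 FPKM; n = 5 and 5), Mrgpra7 rose 4.62 (SE 0.22), Mrgpra4 4.15 (SE 0.20) and Mrgprx1 3.12 (SE 0.20). Of the 12 Mrgpr family members tested 8 rose, 1 fell (Mrgprd) and 3 did not pass, and the list was higher (adjusted p 1.04e-08, and 0.00902 with the correlation between genes estimated from the data). Several of these receptors are close paralogs, so that reads could have been divided among them and the value of a single member is uncertain. Of the 13 markers of the NP2 class of pruriceptors 9 rose and 2 fell (adjusted p 1.57e-07, p = 0.00682 with estimated correlation). The NP2 and Mrgpr family lists share members, among them Mrgprb4, Mrgprx1 and Mrgpra3, whose label the cells were sorted by. Their results are therefore not independent of each other or of the sort. The histamine receptor Hrh1 rose 2.67 (SE 0.24; 20.8 against 2.17 FPKM), whereas Trpa1, an NP2 marker as well, fell to 17.2 from 41.6 FPKM (log2 -1.26, SE 0.19). Outside the family the largest rises were those of the phosphatase Ptpn6 (3.57, SE 0.24), Mustn1 (3.30, SE 0.27), the adenosine receptor Adora2b (3.14, SE 0.24), Rspo1 (3.14, SE 0.22) and the transcription factor Ovol2 (3.06, SE 0.22).

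Markers of the other sensory neuron classes were lower in the MrgprA3+ neurons of control mice. None of the 11 NP3 markers rose and 7 fell (adjusted p 2.18e-06, p = 0.023 with estimated correlation), among them the interleukin 31 receptor Il31ra (5.84 against 54.1 FPKM; log2 -3.40, SE 0.40), Sst (-3.20, SE 0.31), Htr1f (-2.84, SE 0.31) and Nppb (-2.69, SE 0.37). All 8 markers of low-threshold C fibres fell (1.81e-07, p = 0.036 with estimated correlation), Th from 183 to 12.8 FPKM and Zfp521 by 2.41 in log2 (SE 0.25). Of 18 markers of large diameter neurons 15 fell and none rose (1.85e-08, p = 0.0383 with estimated correlation), with Cntn1 (-3.85, SE 0.23), Kcna1 (-3.30, SE 0.32), Ntrk2 (-2.88, SE 0.29) and Nefh (-1.36, SE 0.22). Peptidergic nociceptor markers divided: 11 of 16 fell, such as Kit (-3.82, SE 0.32), Adcyap1 (-2.97, SE 0.29) and Tac1 (171 against 1112 FPKM), and 3 rose, Calca among them (5129 against 3415 FPKM; log2 0.60, SE 0.11). That list was lower with an adjusted p of 3.0e-04, which became 0.0817 with the correlation estimated. NP1 markers as a list did not pass (0.0591): 6 of 11 fell, including Mrgprd (-2.43, SE 0.29) and Grik1 (-2.18, SE 0.24), 1 rose and 4 did not pass, while 3 rose and 7 fell when adjusted over the list alone.

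Among channels and receptors, losses outnumbered gains in the control mice, as they did among all genes past the threshold (1037 higher, 2204 lower). These lists share members with the class marker lists above, such as Scn1a, Kcna1, Il31ra and Sst. Potassium channels had 23 members lower and 5 higher of 43 (adjusted p 0.00842, p = 0.11 with estimated correlation). Kcnk1 fell 3.02 (SE 0.30), and Kcnmb1, a subunit of calcium-activated channels, rose to 166 from 47.3 FPKM. Voltage-gated sodium channels had 8 of 13 lower and 2 higher (0.048, p = 0.267 with estimated correlation, and 0.0566 with the mouse as replicate block). That list did not pass without MrgprA3+ replicate 2, 4 or 5 or MrgprA3- replicate 3 (0.0609, 0.0616, 0.0856 and 0.0724). Scn1a fell 2.62 (SE 0.32) and Scn3b rose 0.74 (SE 0.16). In the TRP list 7 of 17 fell and 1 rose (0.0294, p = 0.141 with estimated correlation), with Trpc4 at -1.85 (SE 0.21) and the capsaicin receptor Trpv1 at -0.57 (SE 0.17). The acid-sensing channel Asic3 had the largest fall of any gene named by the rule (2.58 against 64.4 FPKM; log2 -4.46, SE 0.43), though the list of mechanosensitive and acid-sensing channels, with 7 of 13 lower and 2 higher, did not pass (0.0647). Inhibitory receptors fell as a group, 11 of 15 with 1 higher (2.33e-07, p = 0.00902 with estimated correlation), led by Npy2r (-4.10, SE 0.37), Npy1r (-3.01, SE 0.21) and Cnr1 (-2.61, SE 0.20). Of 21 itch mediator receptors 11 fell and 4 rose (0.0295, p = 0.186 with estimated correlation), and 7 of 12 neuropeptides fell and 2 rose (0.0029, p = 0.246 with estimated correlation).

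Synaptic vesicle genes were lower in 16 of 26 and higher in 1 (adjusted p 1.79e-04, p = 0.0399 with estimated correlation), Sv2b by 3.67 in log2 (SE 0.33) and Snap25 to 371 from 927 FPKM. The sterol synthesis list, which holds enzymes and regulators, fell in 19 of 23 with none higher (6.13e-08, p = 0.0655 with estimated correlation), for example the transcription factor Srebf2 (-1.12, SE 0.16) and the enzyme Sqle (-0.82, SE 0.12). Ribosomal protein genes went the other way, 18 of 53 higher and none lower (8.8e-11, p = 0.246 with estimated correlation), with a median log2 change of 0.35 and Rpl14 at 0.81 (SE 0.11). Of 20 nerve injury genes 9 fell and 2 rose (0.00901, p = 0.246 with estimated correlation): Gal fell 3.08 (SE 0.53) and Atf3 1.65 (SE 0.29), whereas Gap43 rose 0.70 (SE 0.12). Immediate early and stress genes fell in 10 of 20 (0.0294, p = 0.102 with estimated correlation, and 0.053 without MrgprA3+ replicate 4), Zfp36 from 8.76 to 1.11 FPKM. Interferon-stimulated genes did not pass as a list (0.563), with 3 of 27 higher and 3 lower. Ifi27l2a rose 2.48 (SE 0.34), Lgals3bp rose from 66.2 to 143 FPKM and Stat2 fell from 30.96 to 21.4 FPKM. Pan-neuronal genes went in either direction, 4 of 16 higher and 3 lower (0.982). Per library the mean of that list was lower in MrgprA3+ libraries by 0.18 in control and by 0.24 in ACD mice, each with an exact permutation p of 0.00794 (0.0181 adjusted over 32 such tests). List means per library, here and below, were taken without rescaling. Under the deposited scaling the median gene stood at -0.14 in control and -0.12 in ACD mice, so differences of about that size are relative.

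Transcripts listed as glial markers differed between the populations too, though the lists do not show which cells the transcripts came from. Satellite glia markers fell in 8 of 12 (adjusted p 0.00842, p = 0.0817 with estimated correlation) and Schwann cell markers in 7 of 10 with 1 higher (0.016, p = 0.0803 with estimated correlation), S100b from 94.2 to 16.9, Ngfr from 143 to 54.9 and Mbp from 33.2 to 11.1 FPKM. Per library the mean of the satellite glia list was lower in MrgprA3+ libraries by 0.69 and that of the Schwann list by 0.80 in log2, each with an exact permutation p of 0.00794 (0.0181 adjusted over 32 such tests). Macrophage and leukocyte markers, of which 3 of 5 tested fell and 1 rose, did not pass as a list (0.332). Their mean per library was lower by 0.65 (exact permutation p 0.0317, adjusted 0.0634). The MrgprA3+ libraries of control mice held 13448 to 14246 genes above 0 FPKM and the MrgprA3- libraries 15534 to 16163 (exact permutation p 0.00794). The ribosomal RNA gene Rn28s1 averaged 7.91 FPKM (SD 8.53, range 0 to 20.5) in the MrgprA3+ and 242 FPKM (SD 168, range 93.9 to 526) in the MrgprA3- libraries. The 20 highest genes held 18.8% (SD 0.652) and 15.7% (SD 0.769) of the summed FPKM.

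**Figure D1:**
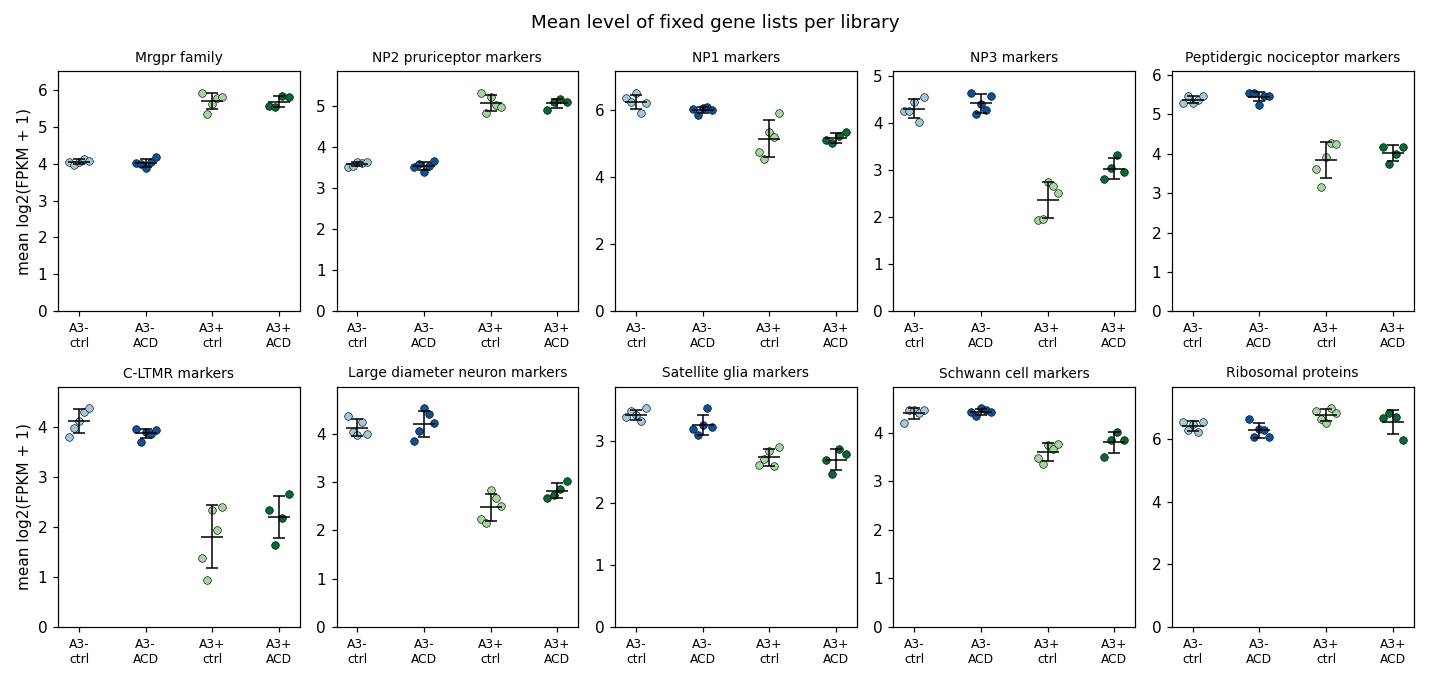
Mean log2(FPKM + 1) of 10 fixed gene lists in each of the 19 libraries, by population and treatment (A3+ and A3-, control and ACD); points are libraries, bars the group mean with its SD. The Mrgpr family and NP2 lists lie higher in the MrgprA3+ libraries, the NP3, peptidergic, low-threshold C fibre, large diameter and glial lists lie lower.

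By limma on log2(FPKM + 1), 3241 of 11996 genes passed an adjusted p of 0.05 in control mice, 1037 higher and 2204 lower in MrgprA3+ neurons (68.0% lower), and 1200 of them changed by at least 1 in log2. Deposited scaling placed the median gene at -0.14, so changes of that size are relative; after median-ratio rescaling 1413 were higher and 1751 lower, and after quantile normalization 1533 and 1529. With the satellite glia and Schwann list means as covariates, which themselves differ between the populations, 96 genes passed. No count with 1 library left out fell below 2580 or rose above 3327, and 3368 genes passed without the MrgprA3+ library of the largest spread in each treatment (replicate 2 in either).

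In ACD mice the same receptors marked the MrgprA3+ neurons. Mrgprb4 was higher by 5.31 in log2 (SE 0.35; n = 4 and 5), Mrgpra7 by 4.59 (SE 0.23), Mrgpra4 by 4.26 (SE 0.21), Ptpn6 by 3.60 (SE 0.25), Adora2b by 3.41 (SE 0.26), the protease Tmprss11c by 2.99 (SE 0.31) and Hrh1 by 2.85 (SE 0.25). The Mrgpr family had 7 of 12 members higher and 1 lower (adjusted p 3.94e-09, p = 0.00721 with estimated correlation), the NP2 markers 8 of 13 higher and 2 lower (3.05e-08, p = 0.00332 with estimated correlation). As in control mice, those lists share members, Mrgpra3 among them. Kit (-3.86, SE 0.34), Sv2b (-3.53, SE 0.35), the transcription factor Pou4f3 (-3.33, SE 0.44), Hhatl (-3.15, SE 0.29), Fxyd6 (-3.06, SE 0.33), Npy2r (-3.03, SE 0.39), Ntrk2 (-3.02, SE 0.30) and Asic3 (-3.02, SE 0.45) were the genes with the largest falls.

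The NP3 list was lower in ACD mice as well, 6 of 11 with none higher (adjusted p 2.12e-04, p = 0.0672 with estimated correlation). Il31ra stood at 14.3 against 70.3 FPKM (-2.30, SE 0.43), Sst at -2.06 (SE 0.33) and Nppb at -2.31 (SE 0.39). Low-threshold C fibre markers fell in 7 of 8 (3.43e-05, p = 0.0779 with estimated correlation), with Th at -2.69 (SE 0.44) and Piezo2 at -1.30 (SE 0.25). Large diameter markers fell in 13 of 18 (1.73e-07, p = 0.0672 with estimated correlation) and peptidergic markers in 12 of 16 with 2 higher (2.11e-04, p = 0.0827 with estimated correlation), Tac1 to 175 from 995 FPKM. NP1 markers did not pass as a list (0.29): Mrgprd fell 2.37 (SE 0.31) and Cd55 rose 0.68 (SE 0.15), with 4 of 11 higher and 6 lower.

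Inhibitory receptors (11 of 15 lower, 1 higher; adjusted p 2.72e-07, p = 0.00721 with estimated correlation), synaptic vesicle genes (15 of 26 lower, 1 higher; 3.43e-05, p = 0.0383 with estimated correlation) and genes of the sterol synthesis list (16 of 23 lower; 9.1e-08, p = 0.0762 with estimated correlation) fell in ACD mice, Nsdhl by 1.14 (SE 0.19). Ribosomal protein genes rose in 10 of 53 (2.72e-07, p = 0.382 with estimated correlation). Potassium channels (23 of 43 lower, 7 higher; 0.0225, p = 0.178 with estimated correlation), TRP channels (7 of 17 lower, 1 higher; 0.0312, p = 0.178 with estimated correlation), itch mediator receptors (8 of 21 lower, 1 higher; 0.0312, p = 0.18 with estimated correlation) and neuropeptides (7 of 12 lower, 2 higher; 0.00896, p = 0.308 with estimated correlation) passed as lower. The TRP list did not pass without MrgprA3+ replicate 4 (0.0789). Trpa1 fell 1.09 (SE 0.20) and Tlr4 1.21 (SE 0.19). Satellite glia markers fell in 4 of 12 (0.0391, p = 0.178 with estimated correlation) and Schwann cell markers in 5 of 10 with 1 higher (0.0391, p = 0.135 with estimated correlation). The satellite list did not pass without MrgprA3+ replicate 2 or 5 or MrgprA3- replicate 4 (0.0762, 0.0532 and 0.074), nor the Schwann list without MrgprA3+ replicate 1 (0.0992). Per library the satellite mean was lower in MrgprA3+ libraries by 0.56 and the Schwann mean by 0.62 (each exact permutation p 0.00794, adjusted 0.0181). Macrophage and leukocyte markers fell in 4 of 5 and did not pass as a list (0.0746). Their mean per library was lower by 1.08 in MrgprA3+ libraries (exact permutation p 0.0159, adjusted 0.0339 over 32 such tests). Rn28s1 averaged 14.03 FPKM (SD 15.9) in the MrgprA3+ and 159 FPKM (SD 28.1) in the MrgprA3- libraries of ACD mice, and the 20 highest genes held 18.7% (SD 0.931) and 15.7% (SD 0.450). The chemokine Ccl2 was lower in MrgprA3+ neurons of ACD mice (0.890 against 4.24 FPKM; adjusted p 0.0137). In control mice it did not pass (0.101), but did with the mouse as replicate block (log2 -0.88) and without MrgprA3+ replicate 5 (-1.32). The test of the difference between treatments did not pass for Ccl2 (adjusted p 0.994). Nerve injury genes (0.077), immediate early genes (0.0819) and cytokines (0.091) did not pass, and did with the mouse as replicate block (0.0258, 0.0456 and 0.0486). With estimated correlation their adjusted p was 0.447, 0.18 and 0.18. Per library the mean of the immediate early list was lower in MrgprA3+ libraries by 0.42 (exact permutation p 0.00794, adjusted 0.0181).

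A total of 2647 genes passed by limma in ACD mice, 821 higher and 1826 lower (69.0% lower; 1137 and 1510 after median-ratio rescaling, 1190 and 1296 after quantile normalization), and 154 with the glial covariates. With 1 library left out the count lay between 2084 and 2988, and without the 2 MrgprA3+ libraries of the largest spread it was 2491. Of the genes higher in control mice, 613 were higher in ACD mice as well (71.0 if the 2 sets were independent), and 1328 were lower in either (336 if independent). Only 1 gene passed in opposite directions, and 97.1% of the genes past the threshold in control mice had the same sign in ACD mice. Across the 11996 genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.823.

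Within the MrgprA3+ neurons, the genes past the threshold between ACD and control mice were no more than simulated data without change gave, and none passed in a fit of those libraries alone. The calcium-binding protein S100a16 was higher in ACD mice by 1.90 in log2 (SE 0.28; 10.02 against 1.98 FPKM; n = 4 and 5), the protease inhibitor Serpinb1a by 1.39 (SE 0.21; 48.9 against 18.6 FPKM), Ces5a by 1.59 (SE 0.23), the cytokine receptor Tnfrsf12a by 1.67 (SE 0.33) and the class II chaperone H2-DMa by 1.34 (SE 0.27). Sytl2 (1.58, SE 0.32) and Nrip3 (1.39, SE 0.28), which are low in MrgprA3+ neurons, were higher too, as were Timm44 (0.87, SE 0.18), Qars (0.83, SE 0.17) and Vat1l (0.52, SE 0.09). Npl (-1.91, SE 0.32), Acsf3 (-1.73, SE 0.32), Csad (-1.67, SE 0.33), the corepressor Rcor1 (-1.67, SE 0.28), Cryl1 (-1.11, SE 0.22) and Zfp277 (-0.92, SE 0.16) were lower. With the replicate number as replicate block Tnfrsf12a (1.58) and Timm44 (0.83) did not pass. None of these passed in a fit of the MrgprA3+ libraries alone, where Serpinb1a had an adjusted p of 0.258 and S100a16 of 0.563.

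By limma over all 4 groups 42 genes passed, 25 higher and 17 lower, with 1642 genes at an unadjusted p below 0.05. Fitted to the MrgprA3+ libraries alone, or with library weights, 0 passed (665 and 770 unadjusted). The median spread of a gene was 0.43 and 0.40 in the MrgprA3+ groups and 0.21 in either MrgprA3- group, and the shared fit applies a single spread to all. In 20 simulated data sets with no change and each population's own spread, that shared fit gave a median of 42 genes (highest 73) and of 1438.5 at an unadjusted p below 0.05. The fit of the MrgprA3+ libraries alone gave 0 (604.5 unadjusted). The observed 42 genes were thus no more than the median of the simulated data. Other splits of the real libraries gave a lower median of 17 genes, and 22 of 100 splits, the real one included, gave at least 42. Fitted alone in simulated data, the test recovered 26.9% of changes of 1 and 75.8% of changes of 2 in log2. Leaving out 1 library moved the count from 20 (without control replicate 2) to 102 (without control replicate 1), and 9 of the 42 genes passed in each of those 9 fits.

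Itch receptors and transducers did not pass with dermatitis in MrgprA3+ neurons: Mrgpra3 stood at -0.26 in log2 (SE 0.15; adjusted p 0.475), Mrgprb4 at 0.38 (SE 0.35; 0.668), Hrh1 at 0.22 (SE 0.25; 0.732), Trpa1 at 0.16 (SE 0.20; 0.763) and Trpv1 at 0.14 (SE 0.18; 0.771). No member of the Mrgpr family or of the NP2, NP1, TRP, cytokine, interferon or JAK-STAT lists passed, and none of those lists passed. The list of itch mediator receptors did not pass either (0.184); 0 of its 21 members passed over all genes, and 3 were higher and 2 lower when adjusted over the list alone. The NP3 list was higher in ACD mice (adjusted p 8.91e-05, median log2 change 0.61), an adjusted p that became 0.181 with the correlation estimated. Its members did not pass one by one, Il31ra at 1.45 (SE 0.43; 0.137), Sst at 0.96 (SE 0.33; 0.191) and Htr1a at 0.64 (SE 0.29; 0.328), while 2 of 11 passed when adjusted over the list alone. Large diameter markers (0.0302, p = 0.716 with estimated correlation), with Cntn1 at 0.95 (SE 0.24; 0.0787), and nerve injury genes (0.0371, p = 0.716 with estimated correlation), with Tubb6 at 2.11 (SE 0.53; 0.0764), were higher as lists. Neither passed without control replicate 1 (0.145 and 0.075) or 2 (0.191 and 0.275) or without ACD replicate 4 (each 0.0803) or 5 (each 0.25), nor nerve injury genes without control replicate 3 (0.0549). Ribosomal protein genes were lower as a list (2.46e-06, p = 0.746 with estimated correlation; median -0.23) with no member past the threshold. That result rested on ACD replicate 5, whose list mean was 5.98 against 6.69 to 6.83 in the other 3 ACD libraries. Without it the mean change of the list was -0.04 (adjusted p 0.673). The fit of the MrgprA3+ libraries alone reuses the same values. In it NP3 (5.39e-05), large diameter (0.0118), nerve injury (0.0118) and ribosomal (7.81e-08) lists passed in the same directions. Low-threshold C fibre markers passed as higher there (0.0488), and not over all groups (0.124, p = 0.716 with estimated correlation).

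**Figure D2:**
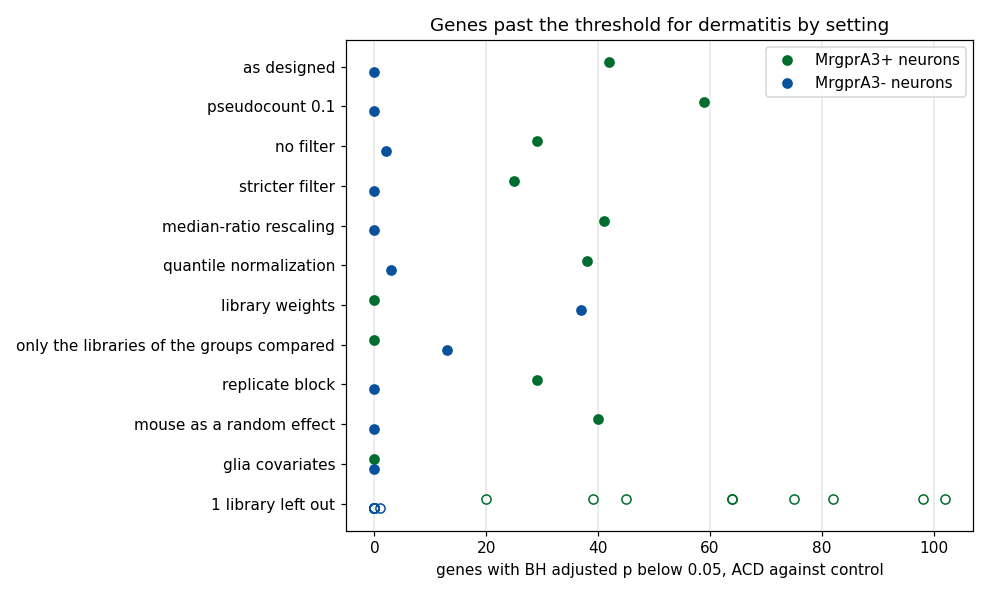
Number of genes with an adjusted p below 0.05 for ACD against control (horizontal axis) under each setting (vertical axis), in MrgprA3+ and MrgprA3- neurons; filled points are whole data sets, open points fits with 1 library left out. The MrgprA3+ count was 42 as designed and 0 with library weights or with only the libraries compared, and the MrgprA3- count was 0, 37 and 13.

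In MrgprA3- neurons 0 genes passed by limma over all 4 groups (214 at an unadjusted p below 0.05), 13 passed in a fit of the MrgprA3- libraries alone (12 higher, 1 lower; 1012 unadjusted), 37 with library weights, 2 without the expression filter and 3 after quantile normalization. The genes with the smallest p did not pass in the shared fit: Tph1, the enzyme of serotonin synthesis (1.06, SE 0.19; adjusted p 0.116), Vat1l (0.45, SE 0.08; 0.116), Galnt6 (1.23, SE 0.25; 0.225), Tifa (39.96 against 19.5 FPKM; log2 1.03, SE 0.22; 0.225) and A2m (1.13, SE 0.24; 0.225). Fitted alone, Galnt6 and Tifa passed at 0.00918, Tph1 at 0.0283 and Vat1l at 0.039. Fam210b, Racgap1 and Accsl (each 0.00918), Serpina3i (0.0165), Zfp772 (0.0383), Steap1 and Smox (each 0.0493) were higher and Prkar2b (0.0383) lower in that fit, genes chosen after their values were seen. In simulated data without change the shared fit gave a median of 0 genes here (160.5 unadjusted). The fit of these libraries alone gave 0 in each of 20 (616). Those data drew each gene independently, and the 13 genes were not set against regroupings of the real libraries.

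In MrgprA3- neurons Mrgpra3 stood at -0.02 (SE 0.14) with dermatitis, Hrh1 at 0.04 (SE 0.24) and Trpa1 at 0.00 (SE 0.19), each with an adjusted p of 1. NP1 markers were lower as a list (adjusted p 6.18e-04, median -0.24), with an adjusted p of 0.625 with the correlation estimated and of 0.0906 without control replicate 3. No member passed, with Cd55 at -0.36 (SE 0.14) and Mrgprd at -0.24 (SE 0.29). Ribosomal protein genes were lower as a list here too (3.56e-04, p = 0.744 with estimated correlation, and 0.125 without ACD replicate 5; median -0.11). Over all groups, other splits of the MrgprA3- libraries gave a median of 6 lists past the threshold, against 2 in the real one. In the fit of these libraries alone, which reuses the same values and was not set against splits, NP1 (3.32e-04) and ribosomal (0.0012) lists were lower. Low-threshold C fibre (0.0105) and satellite glia (0.044) markers also passed as lower there, and NP3 markers (0.0384) and itch mediator receptors (0.044) as higher. Over all groups those 4 did not pass (0.0775, 0.0719, 0.0775 and 0.0775, in that order), and their p with estimated correlation was 0.668 for the C fibre markers and 0.625 for the others. Interferon-stimulated genes did not pass (0.579), Ifit3 at -0.86 (SE 0.23; adjusted p 1), and Ccl2 stood at -0.23 (SE 0.39; adjusted p 1).

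Whether dermatitis acted differently on the 2 populations was tested directly. By limma 0 genes passed (553 at an unadjusted p below 0.05; 0 with library weights, 491 unadjusted), so that no gene can be said to respond in 1 population alone. The genes with the smallest p were Rsc1a1 (1.68, SE 0.37), Ces5a (1.41, SE 0.32), Zfp583 (1.86, SE 0.44), S100a16 (1.58, SE 0.39) and Tspan9 (-1.45, SE 0.37), each with an adjusted p of 0.994. Of the lists, low-threshold C fibre markers (adjusted p 0.0108, p = 0.848 with estimated correlation) and NP3 markers (0.0174, p = 0.848 with estimated correlation) moved higher in MrgprA3+ than in MrgprA3- neurons, with Zfp521 at 1.12 (SE 0.36), Th at 1.37 (SE 0.61) and Sst at 1.14 (SE 0.45), none past the threshold. The C fibre list did not pass without MrgprA3+ control replicate 1 or 2 or ACD replicate 5 (0.0728, 0.16 and 0.121). The NP3 list did not pass without any 1 of MrgprA3+ control replicates 1 and 2, MrgprA3+ ACD replicates 4 and 5 and MrgprA3- ACD replicate 4 (0.0691 to 0.173). Ribosomal proteins moved lower (0.0381, p = 0.982 with estimated correlation, 0.0781 after quantile normalization). Without MrgprA3+ ACD replicate 5 they moved higher instead (mean 0.10; adjusted p 0.363). That list also did not pass without any 1 of MrgprA3+ control replicates 1, 4 and 5, MrgprA3- control replicates 2 and 4 and MrgprA3- ACD replicates 1, 3 and 4 (0.0541 to 0.669). Of the 42 genes past the threshold in MrgprA3+ neurons 33 had the same sign in MrgprA3- neurons (78.6%), and the log2 changes of the 2 populations correlated with a Pearson r of 0.243 across genes, which are not independent replicates.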

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

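The list tests with 1 library left out were chosen after results were seen; the other tests here were chosen before. Values are given where a rule set before the data were examined picked them out, a gap to the nearest library above Dixon's critical value for the group size or a direct test of the difference between populations. Of 188 combinations of 47 values and 4 groups, 7 had a library set apart from its group, and chance alone sets apart about 1 in 20, or 9.4, so the number gives no reason to doubt the libraries as a whole. MrgprA3- control replicate 1 accounted for 3 of the 7. In that library the mean log2(FPKM + 1) of Schwann cell markers was 4.21 (the other 4 libraries 4.41 to 4.48), that of JAK-STAT genes 3.89 (4.01 to 4.03) and that of oxidative phosphorylation genes 6.89 (6.64 to 6.68). MrgprA3+ ACD replicate 5 had the lowest mean of oxidative phosphorylation genes, 6.31 (6.75 to 6.81), MrgprA3+ ACD replicate 4 the lowest Trpv1 value, 6.90 in log2 (7.22 to 7.26), and MrgprA3+ control replicate 2 the lowest mean of TRP channels, 2.24 (2.44 to 2.48). MrgprA3- ACD replicate 3, for which no MrgprA3+ library of that number was analysed here, had an estimated depth of 21.2 M fragments (14.5 to 16.1).

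In a test of the difference between the populations in the change with dermatitis, 3 gene lists passed. NP3 markers (adjusted p 0.0174) and low-threshold C fibre markers (0.0108) had a higher difference in MrgprA3+ than in MrgprA3- neurons, and ribosomal protein genes (0.0381) a lower one. None of the 3 passed with the correlation between genes estimated (0.848, 0.848 and 0.982) or by fry, and 38 of 100 regroupings of the mice gave 3 lists or more (highest other 9), so chance was not excluded. Without MrgprA3+ ACD replicate 5 the ribosomal list turned higher (mean 0.10, adjusted p 0.363). Without that library NP3 (0.0826) and low-threshold C fibre markers (0.121) did not pass either; 16, 14 and 10 of the 19 fits with 1 library left out kept the C fibre, NP3 and ribosomal results.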

How the results depend on the processing

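The 2 libraries left out together, the rescaled lists and the lists with 1 library left out were chosen after results were seen; the other alternatives were planned. Counts past the threshold moved by more than 1.5-fold as follows. For the population difference in control mice, 3241 genes became 96 with glia covariates and 1200 with an absolute log2 change of at least 1; in ACD mice 2647 became 154 and 1096. Glia covariates also turned the sign of Mbp (0.32) and Piezo2 (0.46) in control and of Piezo2 (0.038) in ACD mice. Mbp belongs to the Schwann list whose mean was a covariate, so it was adjusted partly for itself. For Piezo2 the cause was not tested, and no other named gene that passed changed sign under an alternative. For dermatitis in MrgprA3+ neurons, 42 became 25 with the stricter filter and 0 with library weights, with only the libraries of the groups compared and with glia covariates (770, 665 and 1327 at an unadjusted p below 0.05). With 1 library left out that count ran from 20 (without control replicate 2) to 102 (without control replicate 1), with 98 without control replicate 5, 82 without control replicate 4, 75 without ACD replicate 1 and 64 without control replicate 3 or ACD replicate 2. For dermatitis in MrgprA3- neurons, 0 became 2 without the filter, 3 after quantile normalization, 37 with library weights, 13 with only the libraries of the groups compared, and 0 or 1 with 1 library left out (1 without control replicate 1). The interaction stayed at 0 except for 1 gene without MrgprA3+ ACD replicate 5. Lists past the threshold over the 5 comparisons numbered 44 with the preset and 11 with the estimated correlation, and after quantile normalization itch mediator receptors (0.06), sodium channels (0.06) and TRP channels (0.0989) in control mice and satellite glia (0.102) and TRP channels (0.0838) in ACD mice no longer passed. With 1 library left out 38 to 52 lists passed; the adjusted p of ribosomal proteins in the interaction ran from 1.35e-05 to 0.669, and the list turned higher without MrgprA3+ ACD replicate 5 (0.363). With the replicate block, Tnfrsf12a (1.58) and Timm44 (0.83) no longer passed for dermatitis in MrgprA3+ neurons, Ccl2 (-0.88) passed in control mice, oxidative phosphorylation passed as higher in control mice (0.0475 from 0.0827, and 0.633 with the estimated correlation) and 4 lists changed as given with their results. The replicate block changed no other call of a named gene or list and no count by more than 1.5-fold. Without the 2 MrgprA3+ libraries of largest spread the 4 group comparisons gave 3368, 2491, 46 and 0 genes, and 18 of the 42 genes were kept.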

Other observations

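Chosen after results were seen were the tests of the shared spread, of a deviant library, of several neuron classes and of carry-over (both marker sets). The remaining tests below were chosen before their own values were seen. Apart from the counts over splits, they address patterns that were picked from the results. Transcripts listed as endothelial, fibroblast or mural went both ways in MrgprA3+ neurons of control mice (limma, n = 5 and 5). Esam rose from 6.77 to 38.8 FPKM (log2 2.32, SE 0.26), Rgs5 rose 2.08 in log2 (SE 0.22) and Egfl7 0.60 (SE 0.20), whereas Ly6c1 (-1.27, SE 0.31) and Pdgfrb (-1.15, SE 0.40; adjusted p 0.0342) fell. Emcn (adjusted p 0.204), Col1a2 (0.131) and Apod (0.778) did not pass, and the endothelial genes Pecam1 and Cdh5 averaged 0.0200 and 0 FPKM in the MrgprA3+ and 0.928 and 0.0260 FPKM in the MrgprA3- libraries. The class II gene Cd74, a macrophage marker in the lists, fell from 1.74 to 0.0820 FPKM. Copine Cpne6 (10.8 against 171 FPKM), acetylcholinesterase Ache (5.20 against 78.9 FPKM), Fxyd7 (12.6 against 140 FPKM) and Gfra2 (20.7 against 104 FPKM) were further large losses, and the neuropeptide Nts fell 3.44 in log2 (SE 0.50). The intermediate filament Prph rose to 510 from 346 FPKM, and Cacna1h fell from 3.06 to 0.194 FPKM.

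Vat1l and Galnt6 were the genes of the dermatitis comparison that came up in either population. Vat1l was higher in ACD mice in MrgprA3+ neurons (177 against 123 FPKM) and in MrgprA3- neurons (92.1 against 66.9 FPKM), and Galnt6 in the former (2.99 against 0.402 FPKM) and the latter (3.92 against 1.13 FPKM). Each passed in the fit over all groups for MrgprA3+ neurons and in the fit of the MrgprA3- libraries alone, and neither in both populations by the same fit.

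The count for dermatitis was 42 in MrgprA3+ and 0 in MrgprA3- neurons, and 0 genes passed the limma test of the difference between the populations (553 at an unadjusted p below 0.05). With one spread shared by both populations replaced by library weights, 0 of the 42 genes remained, and simulated data without change gave a median of 42, so the shared spread may account for the whole count. The median over other splits of the real libraries was lower, at 17 genes. One deviant library cannot be told apart from this. With 1 library left out the lowest count was 20 (without control replicate 2, with 14 of the 42 genes) and the highest 102 (without control replicate 1). Counts like the lowest arise without any change. The highest lay above the 73 reached in 20 simulated data sets without change and below the 125 reached by another split of the libraries. A change shared by both populations stays open: of the 200 genes with the smallest p in MrgprA3+ neurons 74.5% had the same sign in MrgprA3- neurons, and 1 of 100 regroupings of the mice, the real one, reached that share (highest other 74.0%, median 57.0%). The margin of that test was narrow, and what underlies the shared signs was not tested.

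More genes were lower than higher in MrgprA3+ neurons of control mice, and lower expression in the labelled class itself remains open as untested. Scaling of the deposited FPKM was argued against only for changes of at least 1 in log2, of which 74.8% were lower after median-ratio rescaling. After quantile normalization that excess was smaller (59.3%). Of all genes past the threshold 55.3% were lower after median-ratio rescaling and 49.9% after quantile normalization. Scaling therefore stays open for the excess over all genes. For abundant genes the excess was absent: 48.2% of the 1230 genes past the threshold with a mean of at least 20 FPKM were lower, so fewer genes detected in the MrgprA3+ libraries may explain part of it, although 66.0% of the 200 among them with a change of at least 1 were lower. Several neuron classes in the MrgprA3- gate cannot be told apart from these, because the 73.0% of 63 markers of other classes that fell (18.4% of all genes) restate the lists and are 46 of 2204 lower genes. Glial RNA in the MrgprA3- libraries cannot be told apart either, since within groups the lower genes correlated with the glial score by a median of 0.126, the genes not past the threshold by 0.0492 and the higher genes by -0.0532, and the covariates that left 96 genes were themselves tied to the population.

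NP3 markers were higher in MrgprA3+ neurons of ACD mice by 0.67 in mean log2, and 2 of the 126 splits of the 9 libraries gave as large a difference (exact p 0.0159; highest other 0.70), so chance in the grouping was argued against for this list taken alone and not over the 31 lists tested. Carry-over of MrgprA3- neurons into the sort could bring such transcripts: NP3 markers would need a median share of 10.1% of MrgprA3- RNA, and NP1 and peptidergic markers gave 2.44% (quartiles -1.92 to 11% over 16 genes). Low-threshold C fibre and large diameter markers gave 9.68% (quartiles 1.21 to 25.2% over 20 genes). Those ranges keep carry-over open, and a gain of NP3 transcripts in the labelled neurons with dermatitis remains as an untested hypothesis.

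Other splits of the libraries, 100 drawn from the 126 of each comparison with the real one included, were counted for genes and lists. For the population difference in control mice only the real split gave 3241 genes (highest other 690). That argues against chance for the genes over the splits drawn. For lists 3 of 100, the real one included, gave 19 or more (highest other 21). That share is under 0.05, but 2 other splits gave more lists than the real one. In ACD mice only the real split gave 2647 genes (highest other 1104), which argues against chance over the splits drawn. There 5 splits gave 16 lists or more (highest other 19), which does not. The real splits part every pair of libraries taken as 1 mouse; among the 16 splits that do so the highest other counts were 110 genes and 18 lists in control and 1104 genes and 17 lists in ACD mice, and 16 splits are too few for a share under 0.05. The split with 690 genes parted 3 pairs where the real one parted 5, and that with 1104 parted 4 like the real one.

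For dermatitis, 22 of 100 splits gave at least 42 genes in MrgprA3+ neurons (median of the others 17, highest other 125) and 33 at least 4 lists (highest other 10). All 100 splits reached 0 genes in MrgprA3- neurons (highest other 2) and 95 reached 2 lists (highest other 17). For the interaction, 100 of 100 regroupings of the mice reached 0 genes (highest other 5) and 38 reached 3 lists (highest other 9). Chance was not excluded for the 42 genes or for the 3 counts of lists, and a count of 0 is reached by every split, so those 2 comparisons test nothing. Several splits of the MrgprA3+ libraries, with 125, 120, 118, 111 and 108 genes, lay above the highest of 20 simulated data sets without change (73). What sets them apart was not tested. The simulated data may understate the highest counts that regrouping gives, although their median of 42 genes lay above the median of 17 over the other splits.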
